A study of Mus musculus with 2 samples.

How the data were processed

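H3K27me3 ChIP-seq of forebrain from mouse embryos at 15.5 days was analysed in 2 biological replicates, pools of 78 and 62 embryos of both sexes, per the labels. The list of each replicate merged 2 technical replicates, per the submitters' file notes. The alignments were not used here, and the aligner, the peak caller and its thresholds were not given in the sources used here. The lists of peaks were in narrowPeak format on mm10. Per the file notes, the list of replicate 1 derived from its alignments and 2 other files, and that of replicate 2 from its alignments and 1 other file. The pooled list derived from the alignments of both replicates and the same other files, and the replicated list from the pooled list and both replicates' lists. The labels named a possible control experiment, and the notes did not say whether the other files were its controls. The rule by which peaks were kept as replicated was not given in the sources used here.

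The fold enrichment of each peak is a ratio computed by the authors and deposited in the seventh column of the narrowPeak format. The −log10 p and −log10 q of each peak were deposited by the authors in the next 2 columns. The lowest deposited −log10 p was between 2.00 and 2.03 in the 4 lists. These scores were used as deposited, for filters and ranks and for comparisons within a list, and the highest fold enrichment in each replicated peak was also correlated between the replicates' lists, with −log10 p as an alternative. No read counts were used here, as the lists hold none, so the depth of each sample and the precision it gives are unknown, and no model of counts was fitted.

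Peaks on chromosomes 1 to 19 and X were compared with the protein-coding genes of GENCODE release M21, whose coordinates are on mm10. Overlapping peaks were merged before bases were counted. A promoter was the window of 1 kb to either side of the TSS of any protein-coding transcript, and it was called marked when at least 1 base overlapped a peak. Promoter, exon, intron and intergenic bases were assigned in that order. CpG-rich windows had an observed over expected CpG ratio of at least 0.6 and a GC content of at least 50% in the reference sequence. CpG content was measured in the window at the gene's annotated 5′ end alone, although a gene counted as marked at any of its TSSs. Domains joined replicated peaks at most 3 kb apart. Genes on chromosome Y and on other sequences were left out. Peaks outside the chromosomes analysed were counted and are given in the closing section.

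Replicate overlap was the share of peaks with at least 50% of their length covered by the other replicate's peaks, and the Jaccard index of covered bases. These were compared with 100 placements of the peaks at random on their own chromosomes by bedtools. The 24 gene lists were each compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment. This test takes genes as independent, which neighbouring genes that share a domain are not. Some genes were members of another list as well, such as Eomes (pallial and endoderm) and Olig2 (subpallial and glial). Cover of the 10 kb around the TSS was compared with 10000 random gene sets of the same size by a two-sided permutation test with the same adjustment. The random sets were drawn with replacement from all protein-coding genes, members of the list included. The threshold was an adjusted p of 0.05. The gene lists, tests, thresholds and alternatives were fixed before the data were examined. Tests between pairs of regional lists and of gene families, the counts of noncoding RNAs, the receptors' comparison in each list, the share of covered bases in wide domains, and the restriction to replicated peaks that overlap both replicates' own lists, were added afterwards, as were the tests of the replication rule on X, of low CpG content as the whole cause for receptors and of reads shared between paralogs. Values given as mean ± SD are over the 2 replicates' own lists.

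Genes were named by a rule. In each list these were up to 4 marked members with the most covered bases in the 10 kb around the TSS that were also marked in both replicates, and the first 3 unmarked members in alphabetical order. Also named were the genes of the 5 widest domains, the 10 genes with the highest promoter fold enrichment, up to 5 genes marked in 1 replicate alone by fold enrichment, and Actb and Gapdh. The 20 genes with the most covered bases were summarised by family. Genes named outside this rule are said to be so where they appear.

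Alternatives changed the TSS window, the overlap required, the −log10 q or −log10 p required, the number of peaks, the gap joined, the background genes and the list of peaks used. Leaving out a replicate meant using the other replicate's own list alone. Mappability was assessed by the share of 32-base words of a promoter window that occurred once in the reference genome.

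The tests were tested on simulated data. Of 550 simulated gene lists in each class among 21755 genes, the Fisher's exact test called 41.8% of those simulated with 30% of promoters marked, 90.7% with 50% and 99.6% with 80%. It called 1.45% of the lists simulated at the share of all genes. Genes were simulated as independent of one another, so these rates do not cover neighbouring genes marked together. The coverage test, run here with fewer random sets, called 0% of 20 lists drawn from all genes and 100% of 20 drawn from the most covered 10% of genes. Both outcomes were all but fixed in advance, because 82.8% of genes had no cover and random medians were therefore 0. They do not show how the test behaves on lists with intermediate cover. The overlap counts were wrong in 0 of 200 simulated sets. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, numba 0.67.0 and bedtools 2.31.1 were used.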

Results

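H3K27me3, the histone mark laid down by Polycomb repressive complexes at silent developmental genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the forebrain of mouse embryos at 15.5 days of gestation. The series held 1 group with 2 biological replicates, which were separate pools of strain B6NCrl embryos of both sexes. Replicate 1 came from 78 embryos and replicate 2 from 62 embryos. The labels gave no second tissue, age or treatment, so the comparisons were those between the replicates, between gene lists fixed before the data were examined, and between parts of the genome. The deposited data were lists of peaks, each with its position on mm10, a fold enrichment and its −log10 p and −log10 q. The files gave no read counts, so the sequencing depth behind each peak was unknown, and fold enrichments are the authors' values and were compared only within a list, apart from 1 correlation between the replicates.

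The 4 lists analysed were these: one per replicate, one called on both replicates pooled, and one of the pooled peaks that the authors kept as replicated. Replicate 1 had 43432 peaks covering 16.8 Mb and replicate 2 had 52885 peaks covering 25.02 Mb, or 20.9 ± 5.81 Mb (SD, n = 2). A q below 0.05 was given to 60.3% of the peaks of replicate 1 and 69.9% of those of replicate 2, against 97.7% of the replicated list. Peaks with a higher q were counted as well, also in the shares given below for each replicate. The pooled list had 56707 peaks over 31.6 Mb. The replicated list had 22105 peaks over 21.6 Mb, or 0.819% of the 20 chromosomes analysed, with a median width of 592 bases. Its median fold enrichment was 2.74 and its highest 10.4. Of the replicated peaks, 73.8% overlapped a peak in both replicates' own lists, 18.6% in replicate 2 alone, 5.74% in replicate 1 alone and 1.81% in neither.

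The first comparison asked how far the replicates marked the same sequence. Of the peaks of replicate 1, 49.5% had at least 50% of their length covered by peaks of replicate 2, and 26.4% of the peaks of replicate 2 were covered in this way by replicate 1. When the peaks were placed at random on their own chromosomes, the corresponding shares averaged 1.07% and 0.682% over 100 placements. The Jaccard index of the covered bases was 34.0%, against an average of 0.445% for random placements. No placement reached an observed value, which gave a one-sided permutation p = 0.0099 for each of the measures, the smallest p that 100 placements can give. The placements were uniform along each chromosome outside sequence gaps and did not keep the concentration of peaks at promoters. That p therefore shows more overlap than uniform placement gives and does not measure the quality of the replicates. Across the 16319 replicated peaks that overlapped both replicates' own lists, the highest fold enrichments in the replicates had a Pearson's r of 0.59 on the log2 scale and a Spearman's rho of 0.511. This correlation is across peaks, which are not independent replicates. Most peaks of replicate 2 were therefore not covered in replicate 1, and the gene lists below are given with their share in the replicates' own lists beside the replicated list.

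H3K27me3 lay at promoters far more often than their share of the genome. Windows of 1 kb to either side of protein-coding transcription start sites (TSSs) made up 2.51% of the sequence and held 17.7% of the bases covered by replicated peaks, a ratio of 7.08. In the replicates' own lists this share was 15.2 ± 0.0201% (SD, n = 2). Exons outside promoters held 9.41% of the covered bases against 4.27% of the sequence. Introns held 37.9% against 41.2% and intergenic sequence 34.9% against 52.1%. Counted by gene, 2912 of 21755 protein-coding genes, or 13.4%, had a TSS window overlapped by a replicated peak, and these promoters are called marked here; unmarked means without a replicated peak, although some unmarked promoters had a peak in another list. Replicate 1 marked 2998 promoters and replicate 2 marked 3675, or 15.3 ± 2.20% of the genes (SD, n = 2), with 2638 promoters marked in both. When at least 50% of a window had to be covered, 1647 promoters counted as marked. The promoters of Actb and Gapdh, cytoskeletal and glycolytic genes that all cells use, carried no peak in any of the lists.

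The comparison of gene lists asked which developmental programmes carried the mark in the forebrain. Of 24 lists tested, 16 were marked more often and 2 less often than the other protein-coding genes, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the lists at a threshold of 0.05. Genes that pattern the body axis and the hindbrain were marked throughout. All 39 Hox genes, which set position along the trunk and hindbrain, were marked (adjusted exact p = 8.35e-34). That test counts neighbouring genes that share domains as independent. With each of the 4 clusters counted once, as marked if any of its genes was, the adjusted exact p was 0.000527. A cluster of many genes is more likely than a single gene to pass that rule, so this p does not settle the question. All 30 transcription factors of the midbrain, hindbrain and spinal cord were marked (adjusted exact p = 4.42e-26), as were all 24 of the diencephalon and hypothalamus, which are parts of the forebrain (adjusted p = 4.84e-21), against 13.2 to 13.3% of the other genes in each comparison. In the replicates these lists were marked at 100% for Hox genes, 98.3 ± 2.36% for midbrain, hindbrain and spinal cord factors, and 97.9 ± 2.95% for diencephalic factors (SD, n = 2).

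Within these lists the mark often covered the gene and its surroundings. The 10 kb around the TSS of Hoxa7 were covered entirely by replicated peaks, and in the replicates' own lists at 93.8 ± 8.84% (SD, n = 2). The same was true of Hoxc12, at 96.7 ± 4.64%, Hoxc9, at 97.2 ± 3.96%, and Hoxd11, at 96.6 ± 3.83%. The peak at Hoxa7 spanned 17702 bases and the whole gene, from 52210506 to 52228207 on chromosome 6, with a fold enrichment of 7.88. Evx1, a homeobox gene of spinal interneurons next to the HoxA cluster, was covered at 90.1 ± 5.23% of its 10 kb, and Pax7, a factor of the dorsal midbrain and of muscle precursors, at 89.1 ± 6.93%. Mnx1, a motor neuron factor, was covered at 87.4 ± 11.9% and Sox14 at 84.5 ± 4.16%. Among the diencephalic factors, Hmx2 was covered at 93.4 ± 7.11%, Gbx2 at 83.8 ± 16.7%, Irx3 at 83.1 ± 10.2% and Irx1 at 80.5 ± 20.9% (SD, n = 2 for each).

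Within the telencephalon, regional factors were divided. Of the transcription factors of the subpallium, the ventral part of the telencephalon that forms the basal ganglia and cortical interneurons, 17 of 20 were marked (adjusted p = 2.50e-12, Fisher's exact test), and 87.5 ± 3.54% in the replicates. Examples were Six3, with 98.0% of its 10 kb covered by replicated peaks and 87.4 ± 7.05% in the replicates, Gsx1 with 92.6% (80.3 ± 12.7%), Gsx2 with 89.7% (78.0 ± 10.1%) and Nkx2-1, the factor of the medial ganglionic eminence, with 86.7% (77.6 ± 17.0%). Arx, Ascl1 and Foxp2 were the 3 unmarked members of that list, and Arx, which is on chromosome X, was marked in replicate 2 and in the pooled list. Of the transcription factors of the pallium, the dorsal part that forms the cerebral cortex, and of its excitatory neurons, 9 of 24 were marked, against 13.4% of other genes (adjusted p = 0.00427, Fisher's exact test). The share in the replicates was 47.9 ± 2.95% (SD, n = 2). Replicated peaks covered 93.7% of the 10 kb of Neurog1, 78.7% for Pax6, 68.3% for Neurod2 and 58.5% for Eomes. Cover was lower in replicate 1, at 62.3% for Neurog1, 39.1% for Pax6, 29.6% for Neurod2 and 34.4% for Eomes, than in replicate 2, at 89.6%, 66.2%, 60.8% and 59.0%. Their fold enrichments were 4.23 for Neurog1, 3.52 for Pax6, 2.67 for Neurod2 and 3.11 for Eomes. The unmarked members included Bcl11a, Bcl11b and Cux1. Bcl11a and Bcl11b had no replicated peak within their 10 kb. Cux1 was marked in replicate 2 and in the pooled list, and replicated peaks covered 31.4% of its 10 kb. Foxg1, Emx1, Emx2 and Tbr1, named here after their values were seen, were also unmarked in the replicated list, and Tbr1 was marked in replicate 2. The pallial list was marked less often than the subpallial list (adjusted p = 0.00202), the diencephalic list (adjusted p = 3.59e-06) and the midbrain, hindbrain and spinal cord list (adjusted p = 4.53e-07), in Fisher's exact tests chosen after the lists' values were seen. Among CpG-rich promoters alone, 4 of the 14 pallial promoters were marked against 16.5% of the others, and the list's difference did not pass the threshold (adjusted exact p = 0.313, in a range from 4.95e-05 to 0.313 over all alternatives).

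**Figure D1:**
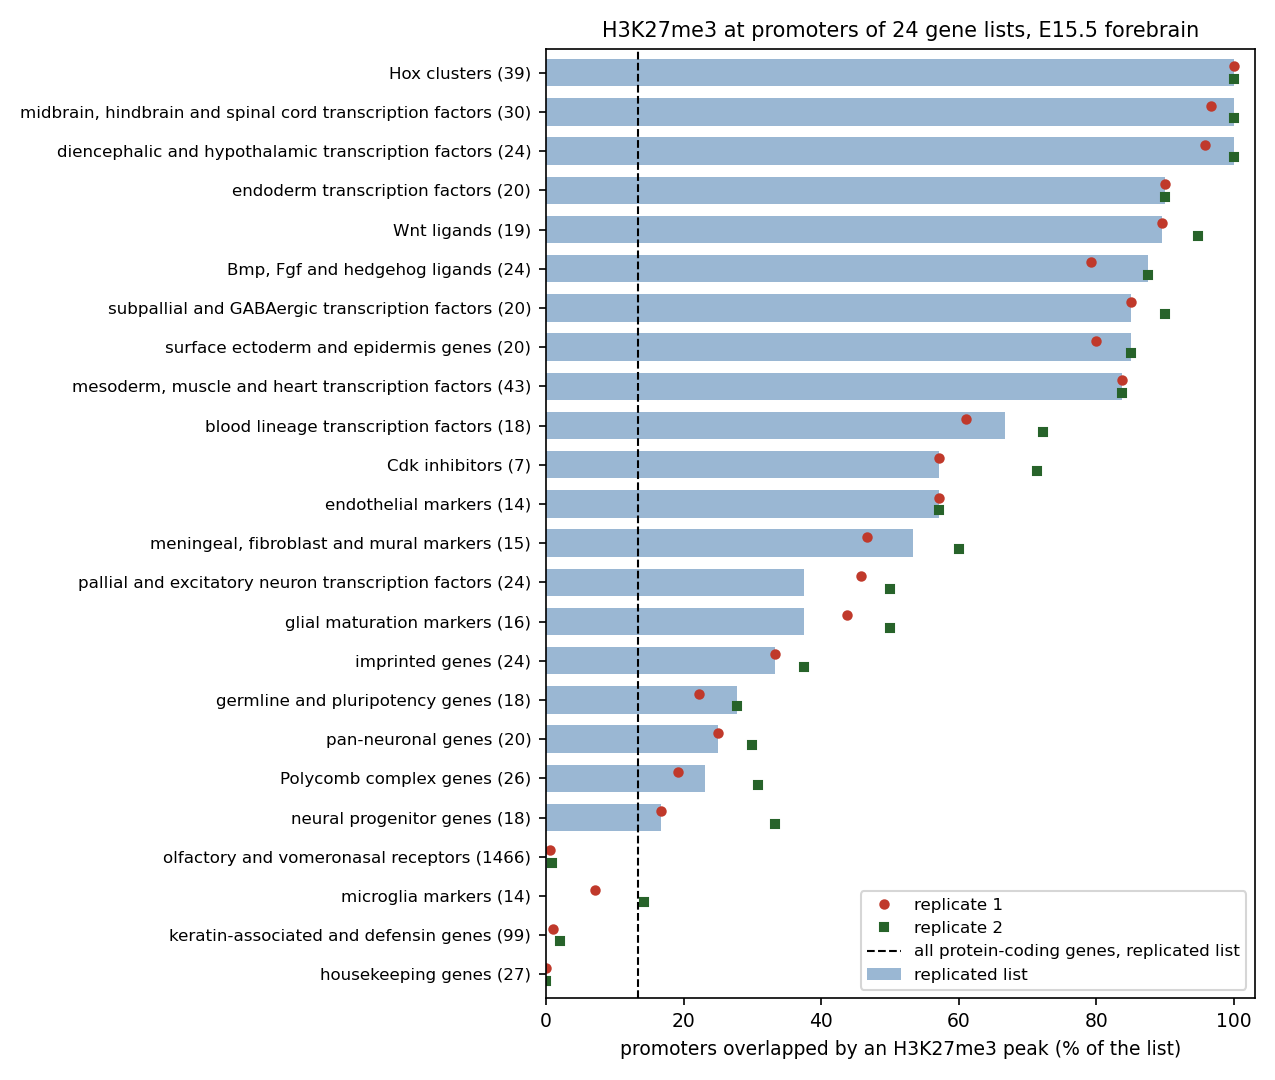
Share of promoters overlapped by an H3K27me3 peak in each of the 24 gene lists, with the number of genes in parentheses. Bars show the replicated list, circles replicate 1, squares replicate 2, and the dashed line the 13.4% of all protein-coding genes in the replicated list. Lists of Hox, hindbrain and diencephalic factors reach 100% in the replicated list, the pallial list 37.5%, and housekeeping genes 0%.

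Lists of factors of tissues outside the nervous system were marked as well, although Eomes, of the endoderm list, was also one of the marked pallial factors. Of the mesoderm, muscle and heart factors, 36 of 43 were marked (adjusted p = 2.21e-24), of the endoderm factors 18 of 20 (adjusted p = 9.04e-14), and of the surface ectoderm and epidermis genes 17 of 20 (adjusted p = 2.50e-12, Fisher's exact tests). The shares in the replicates were 83.7 ± 0%, 90 ± 0% and 82.5 ± 3.54% (SD, n = 2). Examples with nearly complete cover of their 10 kb in the replicated list were Pax9 at 100%, Foxf1, a factor of visceral mesoderm, at 98.2%, Pitx1 at 97.5% and Tbx3 at 96.0%. Among endoderm factors Cdx2 was covered at 100%, Foxa2 at 99.3%, Foxa1 at 98.3% and Foxe1 at 94.9%. Among ectoderm genes Msx2 was covered at 99.4%, Tfap2a at 97.4%, Msx1 at 94.6% and Barx1 at 93.2%. The unmarked members included the muscle factor Myf5, the presomitic mesoderm gene Msgn1 and Meox1, the liver factors Hnf1a and Hnf4a, and the keratins Krt5 and Krt14 with their regulator Trp63; Meox1 was marked in the pooled list. Of the blood lineage factors 12 of 18 were marked (adjusted exact p = 5.98e-07; 66.7 ± 7.86% in the replicates), with Pax5, Gfi1, Ebf1 and Tal1 the most covered and Gata1, Foxp3 and Cebpe among the unmarked, of which Cebpe was marked in the pooled list. Pax5 was also a member of the midbrain, hindbrain and spinal cord list, and Ebf1 of the subpallial list. Germline and pluripotency genes were marked at 5 of 18, which did not pass the threshold (adjusted exact p = 0.0986; 25 ± 3.93% in the replicates). The marked members included Prdm1, Prdm14, Tdgf1 and Pou5f1, and the meiotic and germ cell genes Asz1, Dazl and Ddx4 were unmarked.

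Secreted signals that pattern embryos were another marked group. Of the Wnt ligands 17 of 19 were marked (adjusted p = 5.35e-13) and of the Bmp, Fgf and hedgehog ligands 21 of 24 (adjusted p = 2.31e-15, Fisher's exact tests). The shares in the replicates were 92.1 ± 3.72% and 83.3 ± 5.89% (SD, n = 2). Wnt10b was covered at 95.3% of its 10 kb, Wnt1, the midbrain signal, at 94.4%, Wnt6 at 93.4% and Wnt10a at 92.7%. Gdf7 was covered at 94.2%, Ihh at 92.9%, Shh, the ventral midline signal, at 85.8% and Fgf8 at 83.5%. Wnt5b, Wnt7a, Bmp5, Fgf18 and Gdf5 were the 5 unmarked ligands, although Wnt5b was marked in each replicate's own list and Wnt7a in the pooled list. Of the cyclin-dependent kinase inhibitors 4 of 7 were marked (adjusted exact p = 0.012; 64.3 ± 10.1% in the replicates). Cdkn2a was covered at 91.1% of its 10 kb and Cdkn2b at 80.2%, against 13.0% for Cdkn2c and 12.5% for Cdkn1a. That list fell short of the threshold when only the gene's 5′ end was used (2 of 7, adjusted exact p = 0.238) and ranged from adjusted p = 0.00286 to 0.238 over all alternatives. Of the imprinted genes 8 of 24 were marked (adjusted exact p = 0.0145, in a range from 0.00247 to 0.215), and 35.4 ± 2.95% in the replicates, with Dio3, Grb10, Ascl2 and Phlda2 the most covered and Asb4, Cdkn1c and Igf2r among the unmarked, although Cdkn1c was marked in replicate 2 and in the pooled list and Asb4 in the pooled list. Among CpG-rich promoters 3 of 9 were marked, with adjusted exact p = 0.215.

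Lists for the cell types of the developing brain carried the mark to very different extents. Endothelial markers were marked at 8 of 14 (adjusted p = 0.000266) and meningeal, fibroblast and mural markers at 8 of 15 (adjusted p = 0.000468, Fisher's exact tests). The shares in the replicates were 57.1 ± 0% and 53.3 ± 9.43% (SD, n = 2). In the endothelial list the transcription factors Sox7, Sox17 and Sox18 and the receptor Flt1 were the most covered, whereas the adhesion genes Cdh5 and Pecam1 and the sialomucin Emcn were unmarked. In the meningeal list Foxd1, Foxc1, Col1a1 and Kcnj8 were marked, and Col3a1, Acta2 and Abcc9 were not. Glial maturation markers were marked at 6 of 16 (adjusted exact p = 0.0184; 46.9 ± 4.42% in the replicates). The most covered were Olig1, covered at 92.9% of its 10 kb, Pdgfra at 82.0%, Olig2 at 79.1% and Sox10 at 53.4%, all genes of the oligodendrocyte lineage. Among the unmarked, Aldh1l1 was marked in replicate 2, Aqp4 in the pooled list and the myelin gene Cnp in none of the lists. The lists for progenitors, neurons and microglia did not pass the threshold. Neural progenitor genes were marked at 3 of 18 (adjusted exact p = 0.725), and at 3 in replicate 1 and 6 in replicate 2, with Ccnd1 and Hes1 marked and Fabp7, Hes5 and Hmgb2 unmarked, of which Hes5 was marked in replicate 2. Pan-neuronal genes were marked at 5 of 20 (adjusted exact p = 0.191; 27.5 ± 3.54% in the replicates), with Nefl, Nefm, Camk2b and Grin1 marked and Dcx, Elavl3 and Elavl4 unmarked, of which Elavl3 was marked in the pooled list; in the pooled list 9 of 20 were marked and the difference passed (adjusted p = 0.0067, in a range from 0.0067 to 0.328). Microglia markers were marked at 0 of 14 (adjusted exact p = 0.251), including Aif1, C1qa and C1qb, and at 10.7 ± 5.05% in the replicates' own lists (SD, n = 2).

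Genes used by all cells and the large receptor families were rarely marked. Housekeeping genes were marked at 0 of 27 in the replicated list and in each replicate, among them Actb, Chmp2a and Eef1a1. The difference from 13.4% of the other genes missed the threshold in the replicated list (adjusted p = 0.0531) and passed it in replicate 2 alone (adjusted p = 0.0129) and in the pooled list (adjusted p = 0.0116, Fisher's exact tests, in a range from 0.0116 to 0.3 over all alternatives). Polycomb complex genes were marked at 6 of 26 (adjusted exact p = 0.17; 25 ± 8.16% in the replicates), and the marked members included the chromobox genes Cbx8 and Cbx4, Bmi1 and Phf19, with Aebp2, Cbx2 and Cbx6 among the unmarked. Aebp2 and Cbx2 were marked in replicate 2 and in the pooled list. Olfactory and vomeronasal receptors were marked at 2 of 1466, against 14.3% of the other genes (adjusted exact p = 1.31e-89, the smallest of the 24 lists). That p takes each receptor gene as independent, although neighbouring genes may not be. In the replicates' own lists 8 receptors were marked in replicate 1 and 13 in replicate 2, or 0.546% and 0.887%. The 2 receptors marked in the replicated list were Olfr94 and Olfr63, both on chromosome 17 and both marked in each replicate, with fold enrichments of 3.78 and 2.30. Keratin-associated and defensin genes were marked at 0 of 99 (adjusted exact p = 1.88e-06) and at 1 in replicate 1 and 2 in replicate 2, with unmarked members including Defb1, Defb10 and Defb11.

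A second measure asked how much of the 10 kb around each TSS was covered. Among all protein-coding genes 82.8% had no replicated peak in that window, and 14 of the 24 lists had a median above that of 10000 random gene sets (two-sided permutation test, Benjamini-Hochberg adjustment over the lists). The median was 98.3% for Hox genes, 90.6% for diencephalic factors, 88.7% for endoderm factors, 86.3% for midbrain, hindbrain and spinal cord factors and 80.6% for mesoderm factors. It was 70.9% for subpallial factors, 66.6% for Wnt ligands, 57.6% for ectoderm genes, 44.8% for Bmp, Fgf and hedgehog ligands and 40.01% for endothelial markers, and 17.9% for pallial factors. For these 11 lists the adjusted p was 0.000436, from the smallest two-sided permutation p these random sets can give, 0.0002. The median was 13.0% for cyclin-dependent kinase inhibitors (adjusted p = 0.013), 4.75% for meningeal markers (adjusted p = 0.0024) and 2.67% for blood factors (adjusted p = 0.00295, permutation test). For blood factors it was 1.9% in replicate 1 and 6.46% in replicate 2. The other 10 lists had a median of 0, as the random sets did, so this measure could not show a lower value than random sets for any list. Each of the 14 lists with a median above 0 passed. Passing therefore shows that most members had some cover, and not how much. In 2 kb windows the medians of the pallial factors and of the cyclin-dependent kinase inhibitors were also 0 (adjusted permutation p = 1 for each).

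The 5 widest stretches of the mark lay over the Hox clusters and Nkx2-1. When replicated peaks at most 3 kb apart were joined, they formed 8027 domains with a median width of 1415 bases, of which 634 were 10 kb or wider and 30 were 50 kb or wider. The domains of 10 kb or more, 7.90% of all domains, held 47.3% of the bases covered by replicated peaks, a measure added after the domains were seen; the share was 42.3% in replicate 1 and 47.0% in replicate 2. Of these 634 domains, 344 held the 5′ end of a protein-coding gene. The 4 widest were the Hox clusters. The domain over Hoxc4 to Hoxc13 was 209.9 kb wide (chromosome 15, 102894686 to 103104619). The domain over Hoxa1 to Hoxa13 and Evx1 was 186.5 kb wide (chromosome 6, 52143508 to 52329970). The domain over Hoxb1 to Hoxb9 was 150.3 kb wide (chromosome 11, 96230373 to 96380699), and that over Hoxd1 to Hoxd13 and Evx2 was 127.2 kb wide (chromosome 2, 74642755 to 74769963). The fifth, 113.5 kb wide, held Nkx2-1 as its only protein-coding gene (chromosome 12, 56435540 to 56549060). Peaks of replicate 1 covered 81.7% of the HoxD domain and those of replicate 2 covered 91.6%, and for the Nkx2-1 domain the values were 62.3% and 80.0%. Domains of 10 kb or more held the 5′ end of 2.05% of protein-coding genes. They held that of 39 of 39 Hox genes, 23 of 24 diencephalic factors, 26 of 30 midbrain, hindbrain and spinal cord factors, 14 of 20 subpallial factors and 7 of 24 pallial factors. The number of domains depended on the list, with 18419 in replicate 1 and 19227 in replicate 2.

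**Figure D2:**
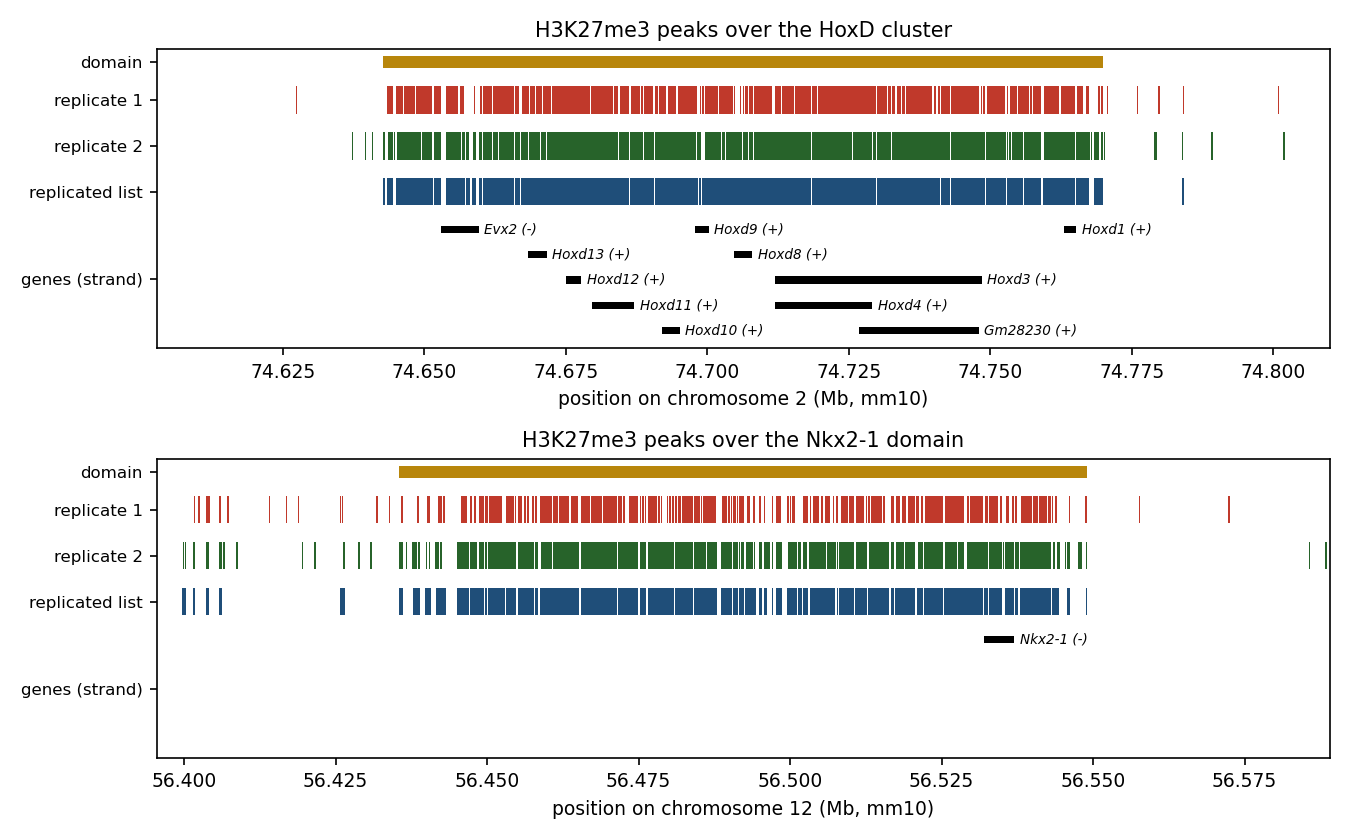
Peaks of replicate 1, replicate 2 and the replicated list over the HoxD cluster on chromosome 2 and the Nkx2-1 domain on chromosome 12, with the joined domain above and protein-coding genes with their strand below; the x axis is the mm10 position in Mb. Both replicates cover most of each domain, and the peaks thin out beyond its ends.

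By cover of the 10 kb around the TSS, the 20 highest genes had between 99.1% and 100% covered, and all 20 were marked in both replicates. They included 9 Hox genes, the homeobox genes Cdx2, Hmx1, Msx2 and Nkx1-1, and Pax9, Foxa2, Skor1, Crlf1, Gfy, Insl3 and Gm28308. By fold enrichment of the promoter peak, the highest in the replicated list was Klf14 at 10.4, with a peak from 30956191 to 30959679 on chromosome 6 over the gene's 5′ end; its 10 kb were covered at 76.4 ± 4.13% in the replicates (SD, n = 2). It was followed by Hoxb6 at 8.82, Hoxb2 at 8.21 and Wnt3a at 7.99. Hoxa3, Hoxa7, Hoxa9 and the protein-coding gene Gm28308 shared 1 peak of 7.88, and Sox18 at 7.67 and Hoxb7 at 7.63 completed the 10 highest. Promoters marked in 1 replicate's own list alone numbered 360 for replicate 1 and 1037 for replicate 2. Those with the highest fold enrichments were Opn1sw, Fam129c, Epha6, Lhx2 and Fbxo41 in replicate 1, at 3.46 to 3.88 in that list, and Rbms1, Gadd45b, Npas4, Lhx9 and Zdbf2 in replicate 2, at 4.74 to 5.28 in that list. Fam129c, Epha6, Lhx2 and all those named for replicate 2 were nevertheless marked in the replicated list. Lhx2 and Lhx9 were thus counted among the marked pallial and diencephalic factors.

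Cover by called peaks differed between chromosomes, and the X chromosome had the least. Replicated peaks covered 0.223% of X against 0.86% of the autosomes together. In replicate 1 the values were 0.253% for X and 0.664% for the autosomes, and in replicate 2 they were 0.438% and 0.985%. X ranked last of 20 chromosomes in each of these lists. The replicated list kept 22.1% of the pooled peaks on X and 39.9% of those on the autosomes, which lowers its value for X. The pools held embryos of both sexes, and cover was not adjusted for the number of X copies. The ranking therefore describes called peaks and not the amount of the mark on X. The mean over the replicates was 0.346 ± 0.131% for X (SD, n = 2), followed by chromosome 3 at 0.439 ± 0.113% and chromosome 16 at 0.477 ± 0.149%. The highest means were 1.49 ± 0.42% for chromosome 11 and 1.48 ± 0.425% for chromosome 19. The means of X and chromosome 3 differed by less than the SD between the replicates, although X was lower in each replicate. No test was made, because the rank of 1 chromosome among 20 cannot give a p under 0.05.

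**Figure D3:**
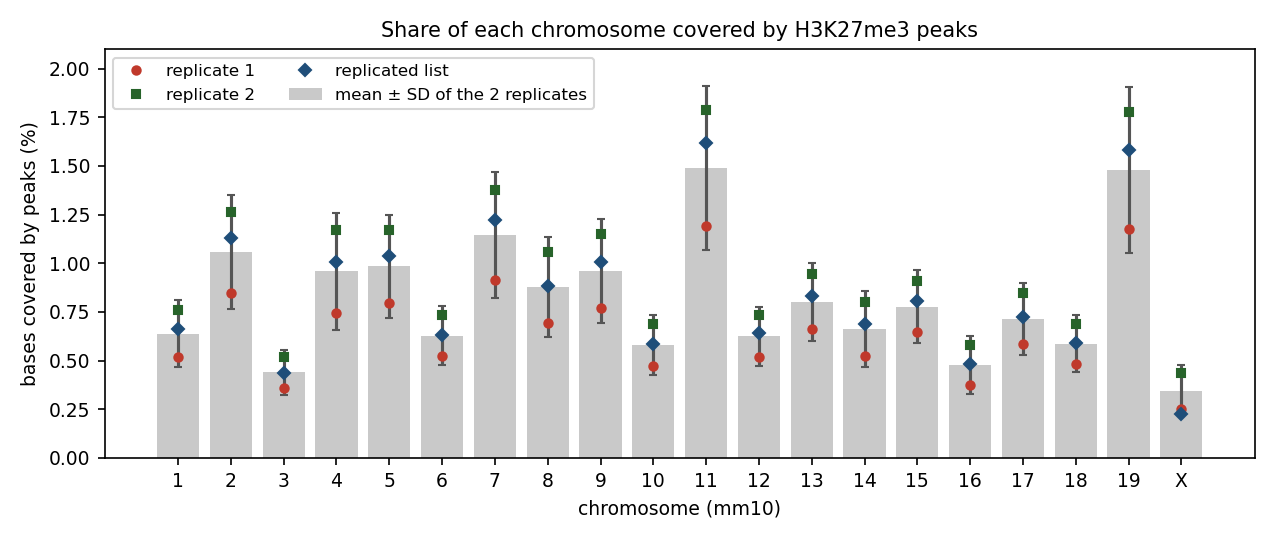
Percent of each chromosome's bases covered by peaks. Grey bars and error bars give the mean ± SD of the 2 replicates, circles replicate 1, squares replicate 2 and diamonds the replicated list. Chromosomes 11 and 19 are highest and X is lowest in each list.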

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

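No test of this part was chosen after a result was seen. The result with data outside the comparisons was 1 peak of replicate 1 on a sequence other than chromosomes 1 to 19 and X, where the other 3 lists had 0. It lay at 54226 to 54410 of an unlocalised sequence of chromosome 4, with a fold enrichment of 2.26 and a −log10 q of 0.586, and it was in none of the counts of genes. A group of 2 replicates is too small for a test of samples far from the others, and the series held no second group to compare. No explanation was tested for this peak.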

How the results depend on the processing

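The restriction to replicated peaks that overlap both replicates' own lists was an alternative chosen after the results were seen. Of the 24 gene lists, 18 passed the threshold and 15 did so under every alternative run. Over all lists and alternatives, 227 results kept their direction and side of the threshold, 5 lost significance, 3 gained it and 3 changed direction. The 13 alternatives for replicate overlap all stayed above every random placement, but the overlap itself depended on the setting. The share of replicate 1 peaks found in replicate 2, 49.5% in the main setting, was 31.998% with at least 90% of the peak covered. It was 62.98% with −log10 q of at least 2. The share of replicate 2 peaks found in replicate 1, 26.4% in the main setting, was 7.29% with at least 90% covered and 37.97% with at least 1 base shared. The Jaccard index ranged from 35.5% to 42.3% over its alternatives. Spearman's rho ranged from 0.5 to 0.561. Depth was unknown, so its effect on the number of peaks could not be assessed.

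With −log10 q of at least 2, replicate 1 kept 18716 peaks, replicate 2 kept 24996 and the pooled list 34644; with −log10 p of at least 5 these were 18277, 19781 and 26332. With at least 50% of the TSS window covered, 1647 promoters were marked. Among CpG-rich promoters alone, which leave fewer genes to test, 28.6% of pallial factors (adjusted exact p = 0.313), 50% of cyclin-dependent kinase inhibitors (0.091), 33.3% of imprinted genes (0.215) and 0% of germline genes (0 of 2) were marked. Cyclin-dependent kinase inhibitors were at 28.6% with at least 50% of the window covered (adjusted exact p = 0.112) and with the 5′ end only (0.238). Microglia markers were at 21.4% with windows of 2.5 kb and in the pooled list, in both cases above the other genes (adjusted exact p = 0.715 and 0.73). Pan-neuronal genes were at 45% in the pooled list, and housekeeping genes were at 0% in the pooled list and without replicate 1. The cause of these changes was not tested.

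With promoters of 2.5 kb to either side, promoters held 36.2% of covered bases, exons 6.15%, introns 28.2% and intergenic sequence 29.5%. Leaving out 1 replicate gave 15.1 to 15.2%, 8.58 to 8.95%, 38.0 to 38.4% and 37.8 to 37.9%. X was covered at 0.253 to 0.438% without 1 replicate and at 0.616% in the pooled list, and it ranked last in each. Without 1 replicate there were 18419 to 19227 domains, of which 649 to 984 were 10 kb or wider. With gaps of at most 1 kb 400 domains were that wide, and with gaps of at most 10 kb 1071. In 2 kb windows the median cover was 0 for pallial factors and 0 for cyclin-dependent kinase inhibitors. Without 1 replicate it was 0 to 1.97% for imprinted genes (adjusted permutation p = 0.0096 without replicate 1) and 0 to 1.00% for glial markers (adjusted permutation p = 0.0227 without replicate 2). The cause of these changes was not tested.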

Other observations

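The tests chosen after results were seen were those of gene families, of the replication rule on X, of low CpG content as the whole cause, of reads shared between paralogs and of the receptors in each list. The test of shared reads replaced a planned test that did not examine the receptors themselves. Among 275 families defined by the stem of the gene symbol, 20 were marked more often and 8 less often than other genes (Fisher's exact tests, Benjamini-Hochberg adjustment). Collagen genes (Col), which build the extracellular matrix and of which 42 of 45 were in no fixed list, were marked at 23 of 45 (adjusted exact p = 6.16e-08; 53.3 ± 9.43% in the replicates). Serotonin receptor genes (Htr) were marked at 9 of 14 (adjusted exact p = 0.000361; 71.4 ± 10.1%) and genes of 2-pore potassium channels (Kcnk) at 8 of 14 (adjusted exact p = 0.00283; 60.7 ± 5.05%). Solute carriers (Slc) were marked at 79 of 371 (adjusted exact p = 0.000483; 24.3 ± 3.43%). Zinc finger genes (Zfp) were marked at 16 of 394, or 4.06% (adjusted exact p = 2.50e-08; 5.20 ± 0.897%), and histone genes (Hist) at 0 of 67 (adjusted exact p = 0.00212), with 0 in each replicate.

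Long noncoding RNA genes farther than 5 kb from any protein-coding TSS were marked at 328 of 9513, or 3.45%, and those within 5 kb at 515 of 3300, or 15.6%. The counts were 445 and 522 in replicate 1 and 544 and 629 in replicate 2. Hotair, a noncoding RNA gene within the HoxC domain (chromosome 15, 102944062 to 102947730), had 97.8% of its 10 kb covered, and Tlx1os, beside the hindbrain factor gene Tlx1, had 98.0%. Both were chosen after their values were seen.

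Peaks of the pooled list on X were in the replicated list less often than autosomal peaks, at 22.1% against 39.9%. Most of this gap went with −log10 p, since autosomal peaks of the same −log10 p were replicated at 28.2%. A lower −log10 p on X was argued against as the whole cause by the remaining deviation of −6.13 points (autosomes from −1.41 to 1.59). Peak width and fold enrichment were not matched, so peaks on X that are weaker or narrower in those measures stay open as a cause of the remainder. Unequal X content of the pools was examined through the share of pooled peaks that overlapped each replicate's own list. X deviated by −0.221 points in replicate 1 and −1.09 in replicate 2, a difference of −0.867 points (autosomes from −2.90 to 2.34). Both deviations lay within the range of the autosomes, so the remainder was absent from these shares. The test therefore cannot decide whether unequal X content caused it. The ratio of replicate 2 to replicate 1 in percent covered was 1.73 on X, above the 1.41 to 1.57 of the autosomes. A difference in X content itself is thus not excluded. The authors' rule for replicated peaks stays open: the share of X peaks with at least 50% covered in both replicates' own lists deviated by −0.694 points (autosomes from −1.48 to 1.10), so the deficit was in the deposited replicated list and not in this overlap, although that test followed values already seen and the rule is not known. No biological explanation was tested, since the labels give no sex difference between the pools.

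Pallial factors were marked at 9 of 24 in a tissue that forms the pallium, with 8 marked and 11 unmarked in the replicated list and both replicates. Overlap at the edge of the window was argued against, because 7 of the 9 stayed marked when at least 50% of a window had to be covered. Cells that do not use the gene may carry the mark: the median fold enrichment of the 9 was 3.00 against 4.67 for the 30 midbrain, hindbrain and spinal cord factors, a difference of −1.67 (permutation p = 0.00016). That lower value is what a mixture of marked and unmarked cells would give, but the data hold no separate cell types, and other reasons for a lower enrichment, such as narrower domains, were not tested.

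Olfactory and vomeronasal receptor promoters were marked at 0.136% in the replicated list, 0.546% in replicate 1 and 0.887% in replicate 2. Low CpG content may account for part of this, since 3.23% of 1889 other promoters with a CpG ratio up to the receptors' 75th percentile were marked, against 14.4% of all 20190 promoters left without receptor, keratin-associated and defensin genes. The receptors' share was 0.0422 times that of those low-CpG promoters (Fisher's exact p = 2.08e-13), and 0.13 times in replicate 1 and 0.178 times in replicate 2 (Fisher's exact p = 1.22e-12 and 1.23e-12). This cannot decide whether low CpG content was the whole cause. The CpG ratio was taken at the gene's 5′ end alone, whereas a gene could be marked at another TSS. Reads shared between paralogs were argued against as the main cause, because among 859 receptor promoters with at least 90% of 32-base words found once in the genome 0.233% were marked (exact 95% upper bound 0.839%), and 0.815% in replicate 1 and 1.28% in replicate 2 (upper bounds 1.67% and 2.28%), each bound being less than 0.5 times the low-CpG promoters' share in the same list. No biological explanation was tested.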
